A study of Mus musculus with 6 samples.

How the data were processed

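Per the labels, microglia, the resident macrophages of the brain, were sorted by flow cytometry from 9-month-old mice. The mice carried 5XFAD, a set of human APP and PSEN1 transgenes with familial Alzheimer mutations that gives early amyloid plaques. The sort used CD11c, the integrin encoded by Itgax, and 3 groups of 2 libraries resulted, namely 5XFAD CD11c+, OPN-KO.5XFAD CD11c+ and 5XFAD CD11c-. OPN-KO names mice without osteopontin, the secreted protein encoded by Spp1. Full-length cDNA was made with SMART-Seq v4 and tagmented with Nextera XT, a chemistry that does not keep the strand.

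The deposited values are raw read counts per gene, in the unit counts, per the file headers and the values themselves, which are whole numbers. The authors name Trimmomatic 0.36, STAR 2.5.2b and Subread 1.5.2 among their tools, with no settings. The column layout of the files is that of featureCounts. Each file lists 49315 genes by Ensembl identifier, and symbols were added for 48970 of them. The genome build is not stated. Of the 49056 identifiers found in a GRCm38 annotation, 44858 had the same start and end there, so coordinates are given as printed in the files and read as GRCm38. No file carried a normalisation.

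Total counts ran from 5657363 to 22607068 per library. The replicate numbers in the labels were taken as names of libraries, not as pairs. The labels do not say whether the 2 libraries of a group come from separate animals or pools, so the p-values measure a spread between libraries. That spread is pooled over all groups and moderated by a prior, so each comparison also carries the spread of the group outside it. In every group the replicates differed by more than sampling noise, with a chi-square per degree of freedom of 34.5 in 5XFAD CD11c+, 82.0 in OPN-KO.5XFAD CD11c+ and 40.5 in 5XFAD CD11c-, over genes with at least 20 counts in the pair.

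Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes were kept by filterByExpr, which left 19897, and libraries were scaled by TMM. A quasi-likelihood model with 1 mean per group was fitted to all 6 libraries, which leaves 3 residual degrees of freedom, to which the prior added 9.14. The biological coefficient of variation was 0.382. The model had no block. The 2 comparisons were 5XFAD CD11c+ minus 5XFAD CD11c-, and OPN-KO.5XFAD CD11c+ minus 5XFAD CD11c+, each with a two-sided F test. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, and a gene was called at an adjusted p under 0.05. The standard error (SE) of a log2 fold change is its size divided by the square root of F. Levels are in CPM (TMM-scaled counts relative to the library total), with the standard deviation (SD) of 2 libraries.

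Before the data were examined, 33 gene lists holding 551 genes were fixed, of which 548 genes were in the files. They were 20 lists of functions, 12 lists of markers of other cell types and 1 list of sex-linked genes. The function lists were homeostatic microglia, disease-associated microglia, interferon response, MHC class II presentation, MHC class I presentation, phagocytic and scavenger receptors, lysosome, cholesterol efflux and lipid handling, cholesterol synthesis, pro-inflammatory mediators, anti-inflammatory and TGF-beta signalling, complement, osteopontin receptors, integrin and matrix adhesion, glycolysis, oxidative phosphorylation, cell cycle, immediate-early and dissociation response, unfolded protein and stress response, and lymphoid and T cell cross-talk ligands. The marker lists were astrocyte, neuron, oligodendrocyte lineage, endothelial and mural, border macrophage, monocyte, neutrophil, dendritic cell, T and NK cell, B cell, erythroid, and ependymal and choroid plexus. Each list was tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists, and again with an estimated correlation. The test with an estimated correlation rests on the 3 residual degrees of freedom, so a list that fails it is not shown to be unchanged. Dendritic cell markers between the CD11c fractions had an estimated correlation of 0.0073, below the preset value. Their adjusted p in the camera test still went from 5.0e-09 to 0.137. Members were also counted with p adjusted over the list alone. Some genes stand in more than 1 list. A further set of 13 neutrophil genes, in none of the lists, was written after the 12 neutrophil markers had been seen to be higher in 5XFAD CD11c-, since those markers cannot test what they had shown.

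The genes named were set by a rule fixed beforehand. It takes the target or sort gene, the 8 called genes with the largest rise and the 8 with the largest fall among annotated genes, and up to 4 members of each list with the smallest p. The largest changes had to have a mean of at least 10 CPM in the higher group and no overlap between the libraries of both groups. Symbols of the Gm, Rik and similar provisional forms were left out of that part. Not every gene the rule gives is printed, and genes named outside it are said to have been chosen after their values were seen.

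The fold changes of both comparisons were correlated across genes and set beside 100 simulations without any group difference that share the 5XFAD CD11c+ libraries. Called genes within 10 Mb of Spp1 were set against all other tested genes by a two-sided Fisher's exact test. For a gene with no count in one group, the fold was computed against a floor of 3 counts over that group and is a lower bound from counting error alone. The reads carry no molecular identifiers, so such a bound does not cover amplification.

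The steps were tested on simulated data with the depth and spread of these libraries and 200 changed genes. A change of 2-fold was called for 1 of 67 genes in the comparison of CD11c fractions and for 3 of 67 in the comparison of genotypes. A change of 4-fold was called for 30 of 67 and 28 of 67 genes, and one of 8-fold for 41 of 66 in both. Of the unchanged genes, 2 of 19131 and 6 of 19017 were called. In all, 74 and 79 simulated genes were called, against 3240 and 1391 in the real libraries. Fewer calls make the adjusted threshold stricter, so the shares of changed genes found can be too low for the real libraries. The list that had been shifted was found in both, where 2 lists were called in the comparison of CD11c fractions and 1 in that of genotypes. Genes were drawn independently in the simulation. In the real libraries the shifted list, homeostatic microglia, had an estimated correlation of 0.43 between the fractions and 0.39 between the genotypes. The simulation therefore cannot show how often the list tests give false calls among correlated genes.

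The alternatives tried were RLE scaling, upper-quartile scaling, DESeq2 1.42.0, no filter beyond 1 count in all, a filter of at least 5 CPM in 2 libraries, a fit of only the 4 libraries compared, the replicate number as a block, and leaving out each of the 6 libraries. A further 2 were chosen after seeing the data. One leaves out the 35 mitochondrial genes. The other, called core scaling here, sets the geometric mean of 5 microglial genes (C1qa, C1qb, C1qc, Hexb, Csf1r) equal in every library. Hexb and Csf1r also stand in the homeostatic list, Hexb in the lysosome list and the C1q genes in the complement list. Counts and medians of those lists under core scaling include them unless said otherwise, and so are in part fixed by that scaling. No library was left out of the values given first. Leaving out a library also lowers the residual degrees of freedom. A call lost that way can reflect lower power and is not shown to rest on that library.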

Results

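The study counted polyA RNA in sorted brain microglia of 9-month-old 5XFAD mice, with 2 libraries in each of 3 groups. Total counts were 16296213 and 15187785 in the 5XFAD CD11c+ libraries, 20419024 and 22607068 in the OPN-KO.5XFAD CD11c+ libraries, and 12226686 and 5657363 in the 5XFAD CD11c- libraries. Mitochondrial genes took 26.5% ± 2.83 (SD, n = 2) of counts in 5XFAD CD11c-, against 1.21% ± 0.448 in 5XFAD CD11c+ and 0.522% ± 0.318 in OPN-KO.5XFAD CD11c+. Along the first principal component, which held 70.4% of the variance, the 3 groups were apart and the 5XFAD CD11c+ libraries lay between the other groups. On the second, which held 12.4%, the 5XFAD CD11c- libraries lay far apart, replicate 1 at -101 and replicate 2 at 58.9. Spp1 (ENSMUSG00000029304, chromosome 5, 104435118 to 104441050) had 5371 and 5780 counts in 5XFAD CD11c+, 1416 and 384 in 5XFAD CD11c-, and 12 and 11 in OPN-KO.5XFAD CD11c+.

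**Figure D1:**
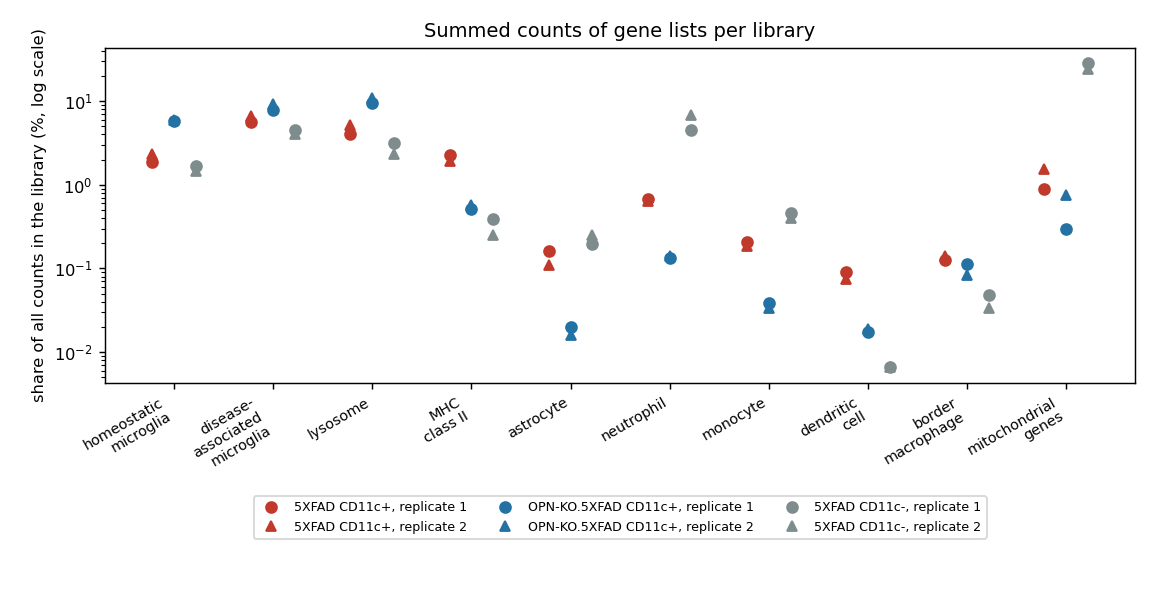
Share of all counts in each library (%, log scale) taken by the summed genes of 9 lists and by mitochondrial genes. Each point is 1 library, circles for replicate 1 and triangles for replicate 2. Astrocyte markers averaged 0.221% in 5XFAD CD11c-, 0.135% in 5XFAD CD11c+ and 0.0179% in OPN-KO.5XFAD CD11c+.

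The first comparison asked how CD11c+ microglia of 5XFAD mice differ from CD11c- microglia of such mice. Of 13 genes of MHC class II antigen presentation 11 were higher in the CD11c+ libraries, among them the invariant chain gene Cd74, with 7029 ± 1221 CPM (SD, n = 2) against 1416 ± 644, a 4.96-fold difference. Higher too were 5 of 12 dendritic cell markers and 9 of 11 border macrophage markers. Among them Cd209a, a lectin of monocyte-derived dendritic cells, was 22.3-fold and the lectin gene Clec10a 13.1-fold above the CD11c- level. The sort chose cells by CD11c and the libraries are bulk. Whether these rises and those of MHC class II lie in microglia or in other cells cannot be told. Of 12 neutrophil markers 11 were lower, with Mmp8, a granule collagenase, at 32.8 ± 4.58 CPM against 1472 ± 204. No list test of this comparison held with an estimated correlation. No homeostatic microglial gene passed between the fractions, and P2ry12, a purine receptor of resting microglia, differed by -1.05 ± 0.39 (log2, SE) with an adjusted p of 0.082. Its adjusted p was 0.0110 with DESeq2, 0.0312 with the replicate block, 0.0455 with upper-quartile scaling and 0.0288 with core scaling, and up to 0.603 when single libraries were left out.

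Itgax (ENSMUSG00000030789, chromosome 7, 128129547 to 128150657), which encodes the sort marker and so is no finding, was 5.20-fold higher in the CD11c+ fraction (log2 fold change 2.38 ± 0.47 SE, adjusted p = 0.0114). The chemokine gene Ccl17 had 200 and 218 counts in the CD11c+ libraries and none in either CD11c- library, at least 52.1-fold higher against a floor of 3 counts over the group. Other large rises were in the lectin gene Cd209c (4.86 ± 0.64), the sphingosine phosphate receptor gene S1pr5 (4.65 ± 0.79), Serpine1, the plasminogen activator inhibitor (4.10 ± 0.59), and Cd300e (3.69 ± 0.63). Among the 8 largest falls that the naming rule gave were Cyp11a1, the enzyme that starts steroid hormone synthesis (-10.69 ± 1.05), the tight junction gene Cldn2 (-8.66 ± 1.42), the basophil proteases Prss34 (-7.88 ± 1.05) and Mcpt8 (-7.50 ± 1.04), and the choroid plexus factor Otx2 (-7.03 ± 0.91). Prss34 was at 324 CPM in 5XFAD CD11c- replicate 1 and 42.9 in replicate 2, and Cyp11a1 at 90.0 and 19.3. Cyp11a1, Prss34, Mcpt8 and Otx2 passed under all 15 alternatives, while Cldn2 could not be tested without 5XFAD CD11c- replicate 1 or with the stricter filter and passed under the other 13.

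Of the 13 genes for MHC class II presentation, 11 were higher, none was lower and 2 did not pass, and the counts were the same when adjusted over the list alone. The transactivator Ciita rose by 3.25 ± 0.36, Cd74 by 2.31 ± 0.42, H2-Eb1 by 2.13 ± 0.36 and H2-DMb2 by 2.11 ± 0.29. The list as a whole was higher than other genes (adjusted p = 2.2e-12), but not with an estimated correlation (adjusted p = 0.269). Of the 14 MHC class I genes, 7 were higher and 7 did not pass, also 7 when adjusted over the list alone, with H2-Q6 at 1.51 ± 0.28 and the peptide transporter gene Tap2 at 1.32 ± 0.31. Without 5XFAD CD11c+ replicate 1 or 2 there were 3 or 6 higher class II genes and no higher class I gene, and 3 of class I without 5XFAD CD11c- replicate 2. With core scaling 7 of class II and 2 of class I were higher. That list had an adjusted p of 1.9e-05 and, with an estimated correlation, an adjusted p of 0.269. Markers of dendritic cells, which express MHC class II strongly, were higher in the same libraries, at 0.0821% ± 0.0118 of counts against 0.00658% ± 6.6e-05.

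Of the 24 homeostatic genes tested with edgeR, none passed in either direction, over all genes or when adjusted over the list alone. At an unadjusted p under 0.05 there were 2 higher and 1 lower, and DESeq2 called 1 higher and 1 lower. The list had a median of -0.24 and a positive test direction, with an adjusted p of 0.646 (adjusted p = 0.953 with an estimated correlation). Of 32 disease-associated genes, those that rise in microglia near plaques, 4 were higher, 1 was lower and 27 did not pass, with the same counts when adjusted over the list alone. The growth factor gene Csf1 rose by 1.58 ± 0.35, Ank by 1.39 ± 0.34 and the receptor gene Axl by 1.41 ± 0.38, while the galectin gene Lgals3 fell by 1.07 on the log2 scale (SE 0.30). The list had an adjusted p of 2.1e-03, which became an adjusted p of 0.547 with an estimated correlation. The 4 higher genes became 0 without either 5XFAD CD11c+ library, 2 without either OPN-KO.5XFAD CD11c+ library and 7 without 5XFAD CD11c- replicate 1, where 3 homeostatic genes were higher.

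The list of immediate-early and dissociation genes, which respond within minutes to stimulation or tissue handling, had 15 of 24 members higher, none lower and 9 not passing, and 20 higher when adjusted over the list alone. The heat shock gene Hspa1b rose by 2.02 ± 0.32 and the nuclear receptor gene Nr4a1 by 2.84 ± 0.48. The list had an adjusted p of 1.4e-13, and an adjusted p of 0.269 with an estimated correlation, and without either 5XFAD CD11c+ library 3 members were higher, or 10 without 5XFAD CD11c- replicate 2. Among 28 pro-inflammatory genes 6 were higher and 22 did not pass, also 6 when adjusted over the list alone, with the inflammasome gene Nlrp3 at 1.91 ± 0.47, the cytokine gene Tnf at 1.70 ± 0.35 and Nfkb2 at 1.48 ± 0.34 (adjusted p = 8.8e-04, and adjusted p = 0.269 with an estimated correlation). Among 26 interferon response genes only Stat2 passed, at 1.61 ± 0.34, also 1 when adjusted over the list alone (adjusted p = 0.00598, and adjusted p = 0.415 with an estimated correlation). There were 0 or 1 higher pro-inflammatory genes without 5XFAD CD11c+ replicate 1 or 2, 3 without 5XFAD CD11c- replicate 2 and 1 with core scaling. The interferon response had 0 without either 5XFAD CD11c+ library and 6 without 5XFAD CD11c- replicate 1.

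Of 26 phagocytic and scavenger receptor genes, 5 were higher and 21 did not pass, 7 when adjusted over the list alone. The scavenger receptor gene Stab1 rose by 2.43 ± 0.37, Lrp1 by 1.76 ± 0.31 and Cd36 by 1.60 ± 0.32 (adjusted p = 9.7e-05, and adjusted p = 0.332 with an estimated correlation). For cholesterol efflux and lipid handling, 4 of 23 genes were higher, 1 lower and 18 did not pass, 6 and 1 when adjusted over the list alone. With upper-quartile or core scaling 2 of these genes were higher, and with DESeq2 7 were. The lipid-sensing factor Pparg rose by 3.44 ± 0.52 and the lipoprotein receptor gene Vldlr fell by 4.39 on the log2 scale (SE 1.12), with an adjusted p of 1.4e-04 for the list and an adjusted p of 0.298 with an estimated correlation. In the lysosome list 1 of 37 genes was higher and 36 did not pass, also 1 when adjusted over the list alone (adjusted p = 5.94e-03, and adjusted p = 0.648 with an estimated correlation). That gene was Atp6v0d2, a proton pump subunit, at 1.34 ± 0.31. Among 21 cholesterol synthesis genes, 3 were higher and 18 did not pass, also 3 when adjusted over the list alone (adjusted p = 0.0548, and adjusted p = 0.322 with an estimated correlation). Core scaling left 1 of them higher, and DESeq2 gave 4. Leaving out single libraries gave 1 to 10 higher receptor genes, 1 to 12 lipid handling genes, 0 to 6 lysosomal genes and 0 to 5 cholesterol synthesis genes. These counts were lowest without 5XFAD CD11c+ replicate 2 and highest without 5XFAD CD11c- replicate 1, and without either OPN-KO.5XFAD CD11c+ library they were 3, 2, 1 and 1. Border macrophage markers, Stab1 among them, were higher in the same libraries, at 0.133% ± 0.0102 of counts against 0.0405% ± 0.0101.

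The list of anti-inflammatory and TGF-beta genes moved both ways, with 7 of 23 higher, 3 lower and 13 not passing, 9 and 3 when adjusted over the list alone. Retnla, a product of alternatively activated macrophages, rose by 3.19 ± 0.58 and the inhibitory factor Smad7 by 2.35 ± 0.42. Il1rn was at -2.50 ± 0.31 and Chil3, also a monocyte marker here, at -2.39 ± 0.40. The list had an adjusted p of 4.55e-03, and an adjusted p of 0.376 with an estimated correlation. Of 9 osteopontin receptor genes 3 were higher and 6 did not pass, 4 higher when adjusted over the list alone. The integrin genes were Itga4 at 2.02 ± 0.40, Itga5 at 1.93 ± 0.37 and Itgav at 1.07 ± 0.33 (adjusted p = 1.15e-03, and adjusted p = 0.269 with an estimated correlation). Itgav did not pass in 9 of 15 alternatives, and 2 receptor genes were higher with RLE, upper-quartile and core scaling and with the stricter filter. In the integrin and matrix adhesion list 4 of 28 genes were higher, 4 lower and 20 not passing, 7 and 4 when adjusted over the list alone (adjusted p = 0.121, and adjusted p = 0.784 with an estimated correlation). That list had 2 higher with upper-quartile or core scaling and 8 with DESeq2. Its largest change was in Mmp9, a gelatinase that neutrophils also store, which fell by 4.53 on the log2 scale (SE 0.38). Of 15 complement genes none was higher, 2 were lower and 13 did not pass, also 2 when adjusted over the list alone, namely Cd55 at -4.15 ± 0.50 and C3 at -1.79 ± 0.31. That list had a median of 0.09 and a mean of -0.06, with an adjusted p of 0.919 (adjusted p = 0.954 with an estimated correlation). The higher genes without 5XFAD CD11c+ replicate 1 or 2 numbered 2 or 1 in the anti-inflammatory list, 0 or 2 among osteopontin receptors and 0 or 2 in the adhesion list, and 1 complement gene was lower. In those lists, complement aside, 11, 5 and 10 were higher without 5XFAD CD11c- replicate 1. The adhesion list had 2 higher without either OPN-KO.5XFAD CD11c+ library or without 5XFAD CD11c- replicate 2.

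Of 26 cell cycle genes 5 were lower and 21 did not pass, also 5 when adjusted over the list alone, with Rrm2 at -2.10 ± 0.34 and Top2a at -1.43 ± 0.31 (adjusted p = 5.01e-03, and adjusted p = 0.269 with an estimated correlation). In glycolysis 1 of 17 genes, Gpi1 (-1.15 ± 0.29), was lower, also 1 when adjusted over the list alone (adjusted p = 0.910, and adjusted p = 0.954 with an estimated correlation). In the unfolded protein list 1 of 17, Asns (-2.33 ± 0.44), was lower, also 1 when adjusted over the list alone (median 0.28, mean -0.02, adjusted p = 0.323, and adjusted p = 0.814 with an estimated correlation). Among 31 oxidative phosphorylation genes, all encoded in the nucleus, edgeR called none over all genes or when adjusted over the list alone. None had an unadjusted p under 0.05 and DESeq2 called none (adjusted p = 0.390, and adjusted p = 0.943 with an estimated correlation). Among 13 lymphoid and T cell cross-talk ligands edgeR called none over all genes or when adjusted over the list alone, with 4 higher at an unadjusted p under 0.05 and 1 higher by DESeq2 (adjusted p = 0.0282, and adjusted p = 0.269 with an estimated correlation). Lower cell cycle genes numbered 1 or 0 without 5XFAD CD11c+ replicate 1 or 2, and 2 without either OPN-KO.5XFAD CD11c+ library. Glycolysis had 0 lower without any of these 4 libraries and 2 without 5XFAD CD11c- replicate 2. The unfolded protein list had 0 lower without 5XFAD CD11c+ replicate 2 and 2 without 5XFAD CD11c- replicate 1, and the cross-talk ligands 4 or 2 higher without 5XFAD CD11c- replicate 1 or 2.

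Markers of other cell types moved apart between the fractions. Neutrophil markers were lower in CD11c+ for 11 of 12 genes, with 1 not passing, and also for 11 when adjusted over the list alone. Ly6g fell by 4.63 on the log2 scale (SE 0.36), Mmp8 fell by 5.49 (SE 0.42) and Retnlg fell by 5.05 (SE 0.50), and the list had an adjusted p of 2.3e-27 and an adjusted p of 0.137 with an estimated correlation. Monocyte markers had 2 of 12 higher and 5 lower, the same when adjusted over the list alone (adjusted p = 0.0132, and adjusted p = 0.415 with an estimated correlation). Dendritic cell markers had 5 of 12 higher and 7 not passing, 7 higher when adjusted over the list alone, with Flt3 at 3.44 ± 0.43 and Klrd1 at 3.16 ± 0.37 (adjusted p = 5.0e-09, and adjusted p = 0.137 with an estimated correlation). Border macrophage markers had 9 of 11 higher and 2 not passing, 9 higher and 1 lower when adjusted over the list alone, with Siglec1 at 2.48 ± 0.43 and Cd163 at 1.88 ± 0.36 (adjusted p = 1.0e-09, and adjusted p = 0.269 with an estimated correlation). Without 5XFAD CD11c+ replicate 1 or 2 there were 4 or 2 higher border macrophage markers, 11 or 10 lower neutrophil markers and 3 lower monocyte markers, and without 5XFAD CD11c- replicate 2 there were 8 higher dendritic cell markers.

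Among markers of brain cells other than microglia the calls were of lower levels in the CD11c+ fraction, but for 1 oligodendrocyte lineage marker. Of astrocyte markers 7 of 12 were lower, 8 when adjusted over the list alone, with Clu at -2.58 ± 0.41 (adjusted p = 1.4e-05, and adjusted p = 0.293 with an estimated correlation). Of neuron markers 7 of 12 were lower, also 7 when adjusted over the list alone, with Snap25 at -2.55 ± 0.44 (adjusted p = 6.9e-05, and adjusted p = 0.375 with an estimated correlation). Of oligodendrocyte lineage markers 5 of 11 were lower and 1 higher, 6 and 1 when adjusted over the list alone, with Plp1 at -2.67 ± 0.48 (adjusted p = 0.00598, and adjusted p = 0.269 with an estimated correlation). Of endothelial and mural markers 5 of 11 were lower, also 5 when adjusted over the list alone (adjusted p = 2.8e-03, and adjusted p = 0.269 with an estimated correlation). Of ependymal and choroid plexus markers 5 of 6 were lower, also 5 when adjusted over the list alone (adjusted p = 4.3e-04, and adjusted p = 0.269 with an estimated correlation). Lower markers without 5XFAD CD11c+ replicate 1 or 2 numbered 2 or 0 for astrocytes, 3 or 0 for neurons, 3 or 0 for the oligodendrocyte lineage and 1 for endothelial and mural cells. Without OPN-KO.5XFAD CD11c+ replicate 1 there were 4 for neurons and 3 for the oligodendrocyte lineage, and without either OPN-KO.5XFAD CD11c+ library 3 for endothelial and mural cells. There were 3 for neurons without 5XFAD CD11c- replicate 2, and without replicate 1 there were 3 for ependyma and choroid plexus. Of the last list Ttr, the main product of the choroid plexus, had 38459 counts in 5XFAD CD11c- replicate 1 and 1846 in replicate 2.

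Of the remaining lists, T and NK cell markers had 1 of 15 higher, also 1 when adjusted over the list alone (adjusted p = 0.874, and adjusted p = 0.954 with an estimated correlation). B cell markers had 2 of 7 lower, also 2 when adjusted over the list alone (adjusted p = 0.175, and adjusted p = 0.571 with an estimated correlation). Erythroid markers had 2 of 6 higher and 1 lower, 5 and 1 when adjusted over the list alone (adjusted p = 0.0145, and adjusted p = 0.415 with an estimated correlation). Of the 5 sex-linked genes 1 was higher, Xist at 1.79 ± 0.41, also 1 when adjusted over the list alone (median -0.04, mean 0.55, adjusted p = 0.181, and adjusted p = 0.560 with an estimated correlation). These counts also changed when single libraries were left out. The OPN-KO.5XFAD CD11c+ libraries are not part of this comparison. A change without one of them can come only through the shared filter, scaling and estimate of the spread. The 1 T and NK cell marker was lost without any 1 of the 4 CD11c+ libraries, and the 1 sex-linked gene without 5XFAD CD11c+ replicate 2. Lower B cell markers ranged from 0 without 5XFAD CD11c+ replicate 1 to 4 without 5XFAD CD11c- replicate 2, and higher erythroid markers from 0 without 5XFAD CD11c+ replicate 2 to 4 without 5XFAD CD11c- replicate 2, with 1 of each without either OPN-KO.5XFAD CD11c+ library.

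Over all 19897 genes tested, 931 were higher and 2309 lower in CD11c+, and 16657 did not pass. Of these calls, 289 higher and 2052 lower genes differed over 4-fold. With the filter of at least 5 CPM in 2 libraries, 441 were higher and 794 lower, of 11561 tested. Genes with any count numbered 26382 and 31911 in 5XFAD CD11c- replicates 1 and 2, and 26068 and 27041 in 5XFAD CD11c+. The 5XFAD CD11c- library with 31911 had the fewest counts of all libraries. By the list tests 15 of 33 lists were higher and 8 lower, and none of the 23 calls held with an estimated correlation. That second test rests on 3 residual degrees of freedom, so it cannot decide whether the calls are sound. The share of calls that were higher was 28.7%, and 12.4% with core scaling, and the median log2 fold change of all genes was -0.15, against -0.34 with upper-quartile scaling and -0.41 with core scaling. Leaving out 5XFAD CD11c+ replicate 1 or 2 left 102 or 190 higher and 278 or 250 lower genes. Without OPN-KO.5XFAD CD11c+ replicate 1 or 2 there were 525 or 581 higher and 908 or 985 lower, and without 5XFAD CD11c- replicate 1 there were 2281 higher.

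**Figure D2:**
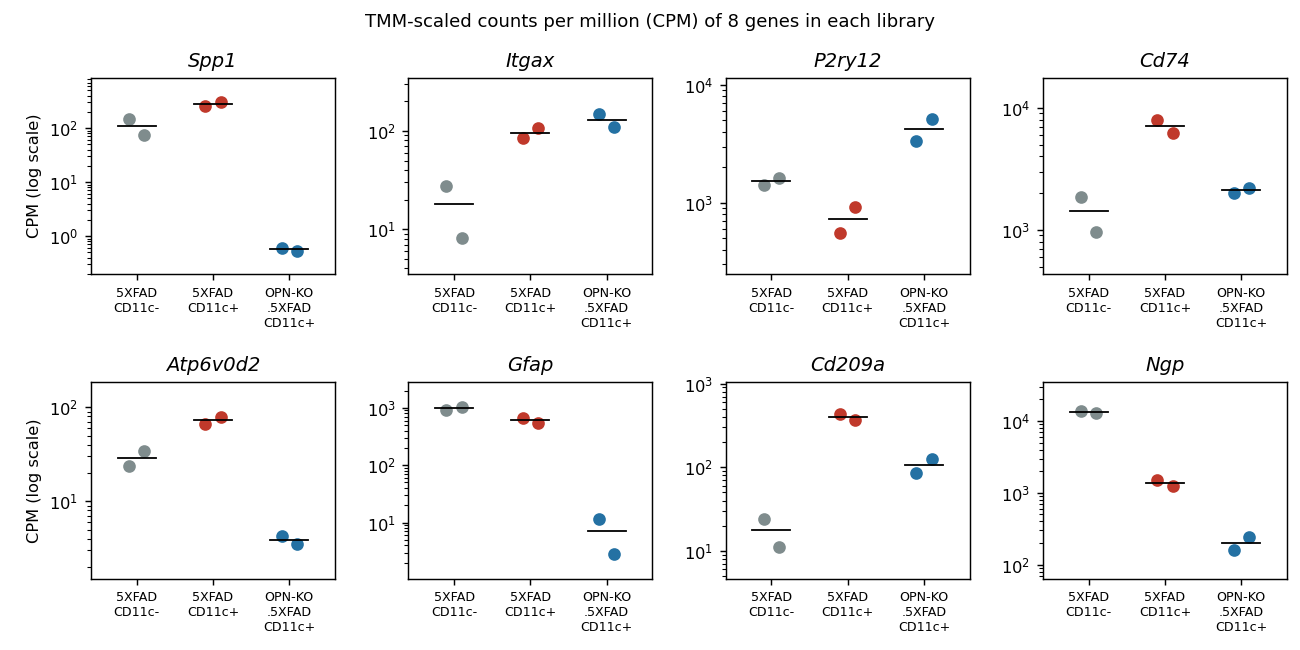
Level of 8 genes in every library, in TMM-scaled CPM on log axes with a range of their own. Each point is 1 library and each bar the mean of 2. Spp1 lies at 0.568 CPM on average in OPN-KO.5XFAD CD11c+ and at 284 in 5XFAD CD11c+, Gfap at 7.20 and 607, and P2ry12 at 4248 and 734.

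The second comparison asked what the loss of osteopontin changes in CD11c+ microglia of 5XFAD mice. Spp1 was 493-fold lower in the knockout libraries (log2 fold change -8.95 ± 0.50 SE, adjusted p = 8.5e-06). Of 24 homeostatic genes 16 were higher in the knockout, with the purine receptor genes P2ry12 and P2ry13 5.79-fold and 5.57-fold above 5XFAD, and so were 20 of 37 lysosomal genes. Core scaling took the median of the first list from 1.73 to 0.13 and that of the second from 1.43 to -0.18. With the core genes themselves left out of the lists, these medians under core scaling were 0.067 and -0.22. The median of all genes went from -0.14 to -1.73, a shift that every value under that scaling carries. Of 13 MHC class II genes 6 were lower and 1 higher, with Ciita 5.05-fold and Cd74 3.32-fold below 5XFAD. Of 12 astrocyte markers 11 were lower, with Gfap, the astrocyte filament, at 7.20 ± 6.17 CPM (SD, n = 2) against 607 ± 76.3, and 10 of 12 monocyte, 10 of 12 neutrophil and 4 of 12 dendritic cell markers were lower as well. No list test of this comparison held with an estimated correlation.

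Among the genes the naming rule covers, with a mean of at least 10 CPM in the higher group, the largest rise was in Angptl7, an angiopoietin-like secreted protein, at 113 ± 3.52 CPM against 4.76 ± 1.45 (log2 fold change 4.56 ± 0.35 SE, adjusted p = 1.3e-04). The immunoglobulin genes Igha (4.43 ± 0.66) and Igkc (3.80 ± 0.56) and the B cell chemokine gene Cxcl13 (3.59 ± 0.46) were also among the largest of these rises. Among the largest falls after Spp1 were Gfap (-6.40 ± 0.61), the myelin gene Mobp (-6.03 ± 0.82), and 2 neighbouring genes of the tripartite motif family on chromosome 7. Trim12a (ENSMUSG00000066258, 104299894 to 104315466) fell by 8.21 on the log2 scale (SE 0.54), with 998 and 1096 counts in 5XFAD CD11c+, 435 and 280 in 5XFAD CD11c- and 1 and 6 in OPN-KO.5XFAD CD11c+. Trim5 (ENSMUSG00000060441, 104263386 to 104288094) fell by 6.08 (SE 0.58). Trim30d and Gm1966, chosen after their values were seen, lie in the same region, where Trim30d fell by 4.97 (SE 0.42) and Gm1966 fell by 7.35 (SE 0.63). Trim34b, chosen likewise, was 2.98 ± 0.68 higher.

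**Figure D3:**
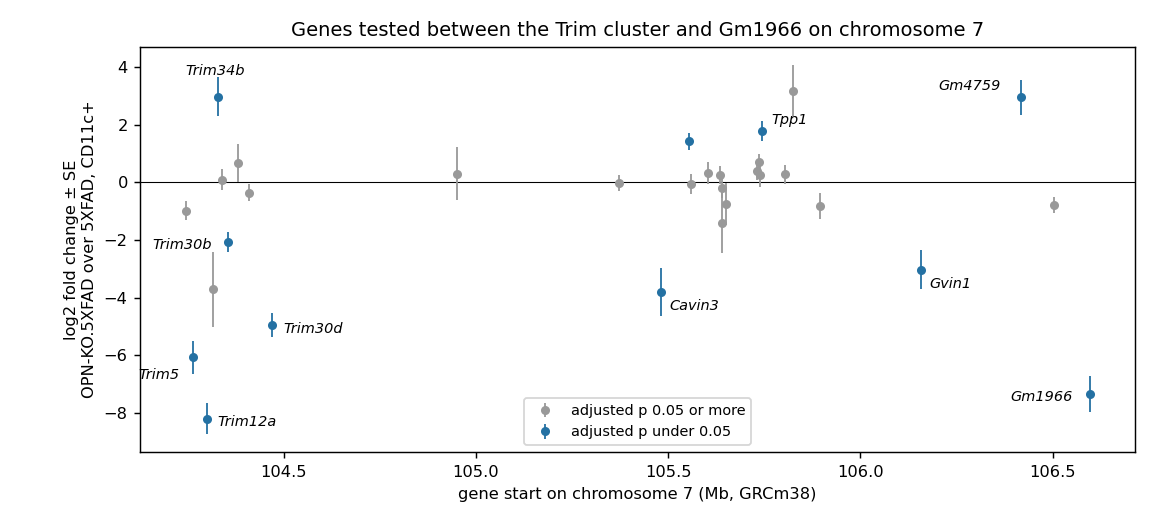
Log2 fold change of OPN-KO.5XFAD over 5XFAD CD11c+ libraries (points, with bars of 1 SE) against gene start on chromosome 7, for tested genes with a mean of at least 1 CPM in either group. Trim12a at -8.21 and Gm1966 at -7.35 lie lowest, next to genes near 0.

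Of 24 homeostatic genes 16 were higher, none was lower and 8 did not pass, and 21 were higher when adjusted over the list alone. P2ry12 rose by 2.53 ± 0.41, P2ry13 by 2.48 ± 0.37, the adhesion receptor gene Adgrg1 by 1.90 ± 0.31 and Ecscr by 1.79 ± 0.30. Tmem119, a microglial surface marker chosen after its values were seen, rose by 2.04 ± 0.38. As a whole the list had an adjusted p of 1.1e-25, and an adjusted p of 0.209 with an estimated correlation. The list took 5.82% ± 0.0977 of counts in the knockout and 2.08% ± 0.324 in 5XFAD, while astrocyte markers took 0.0179% ± 2.5e-03 and 0.135% ± 0.0356 and neutrophil markers 0.138% ± 6.9e-03 and 0.662% ± 0.0301. With core scaling 2 homeostatic genes were higher and 5 lower. Without 5XFAD CD11c+ replicate 1 or 2 there were 0 or 3 higher, and without OPN-KO.5XFAD CD11c+ replicate 1 or 2 there were 10 or 5.

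Of 37 lysosomal genes 20 were higher, 1 was lower and 16 did not pass, 28 and 2 when adjusted over the list alone. The acid hydrolase genes Glb1 (1.95 ± 0.30), Gaa (1.92 ± 0.34) and Gba (1.51 ± 0.29) were higher, with Gba at -0.094 under core scaling. Atp6v0d2, a subunit of the proton pump best known from osteoclasts, fell by 4.22 on the log2 scale (SE 0.35), from 72.4 ± 9.49 to 3.88 ± 0.502 CPM. The lysosomal list had an adjusted p of 6.4e-20, and an adjusted p of 0.316 with an estimated correlation. With core scaling none was higher and 11 were lower, and without 5XFAD CD11c+ replicate 1 or 2 there were 0 or 2 higher, and 4 or 3 without OPN-KO.5XFAD CD11c+ replicate 1 or 2.

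Of 32 disease-associated genes 9 were higher, 2 lower and 21 did not pass, 11 and 2 when adjusted over the list alone, with a list median of 0.66 that was -0.91 under core scaling. The lipase gene Lpl rose by 1.83 ± 0.34 and the adhesion gene Cadm1 by 1.58 ± 0.31 (-0.022 under core scaling), while Lgals3 fell by 1.73 on the log2 scale (SE 0.30) and the fatty acid carrier gene Fabp5 fell by 1.71 (SE 0.36). The list had an adjusted p of 5.8e-06, and an adjusted p of 0.386 with an estimated correlation, and the 9 higher genes became 0 without either 5XFAD CD11c+ library and 3 or 0 without OPN-KO.5XFAD CD11c+ replicate 1 or 2. Of 26 phagocytic and scavenger receptor genes 4 were higher and 22 did not pass, 12 higher and 1 lower when adjusted over the list alone, with a median of 0.84 that was -0.75 under core scaling. Pros1, a bridge to dying cells, rose by 2.03 ± 0.32 and its receptor gene Mertk by 1.47 ± 0.36 (-0.088 under core scaling), with an adjusted p of 5.8e-06 for the list and an adjusted p of 0.359 with an estimated correlation. Of 23 lipid handling genes 3 were higher, 2 lower and 18 not passing, 3 and 3 when adjusted over the list alone, Fabp3 among the lower at -1.54 ± 0.34 (adjusted p = 0.134, and adjusted p = 0.669 with an estimated correlation). Of 21 cholesterol synthesis genes 1 was higher, Msmo1 at 1.33 ± 0.37 (-0.26 under core scaling), and none when adjusted over the list alone (adjusted p = 0.0749, and adjusted p = 0.359 with an estimated correlation). Higher phagocytic receptor genes numbered 0 or 1 without 5XFAD CD11c+ replicate 1 or 2, 1 without either OPN-KO.5XFAD CD11c+ library and 13 without either 5XFAD CD11c- library. With core scaling none of the genes in these 4 lists was higher, and 15 disease-associated, 11 phagocytic receptor, 17 lipid handling (median -1.16) and 14 cholesterol synthesis genes (median -1.57) were lower. Lipid handling had 0 higher without 5XFAD CD11c+ replicate 1 or 2 and 1 or 0 without OPN-KO.5XFAD CD11c+ replicate 1 or 2. Cholesterol synthesis had 0 without any 1 of these 4 libraries and 3 without either 5XFAD CD11c- library.

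Of 13 MHC class II genes 6 were lower, 1 higher and 6 did not pass, the same when adjusted over the list alone. Ciita was at -2.34 ± 0.33, H2-Eb1 at -2.02 ± 0.36 and H2-DMb2 at -1.56 ± 0.28, with an adjusted p of 3.1e-03 for the list and an adjusted p of 0.541 with an estimated correlation. Dendritic cell markers fell in the same libraries, to 0.0179% ± 1.1e-03 of counts from 0.0821% ± 0.0118. Without 5XFAD CD11c+ replicate 1 or 2 there were 1 or 2 lower MHC class II genes, and without OPN-KO.5XFAD CD11c+ replicate 1 or 2 there were 1 or 0. Of 14 MHC class I genes edgeR called none over all genes or when adjusted over the list alone, with 2 higher at an unadjusted p under 0.05 and 2 higher by DESeq2 (adjusted p = 0.134, and adjusted p = 0.669 with an estimated correlation). Of 26 interferon response genes edgeR also called none either way, with 1 higher and 7 lower at an unadjusted p under 0.05 and 4 lower by DESeq2 (adjusted p = 0.134, and adjusted p = 0.669 with an estimated correlation). Without either 5XFAD CD11c- library 2 class I genes and 1 interferon response gene were higher. With core scaling 11 class I genes (median -1.37), 25 interferon response genes (median -1.85) and 11 class II genes were lower and none was higher.

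Of 28 pro-inflammatory genes 6 were higher, 2 lower and 20 did not pass, 7 and 3 when adjusted over the list alone, with a median of 0.26 that was -1.35 under core scaling. The cytokine gene Il1a rose by 2.06 ± 0.29, the receptor gene Tlr4 by 1.78 ± 0.30 and the chemokine gene Ccl4 by 1.43 ± 0.33 (-0.18 under core scaling), while Il1b fell by 1.61 on the log2 scale (SE 0.35). The pro-inflammatory list had an adjusted p of 0.0111, and an adjusted p of 0.359 with an estimated correlation. Of 23 anti-inflammatory and TGF-beta genes 2 were higher, 4 lower and 17 not passing, 6 and 5 when adjusted over the list alone. Retnla fell by 4.83 on the log2 scale (SE 0.62) and Chil3, also a monocyte marker here, fell by 2.94 (SE 0.41). The receptor gene Tgfbr2 rose by 1.89 ± 0.34. The list had a median of 0.47 and a mean of -0.21 (adjusted p = 0.425, and adjusted p = 0.820 with an estimated correlation). Of 15 complement genes 3 were higher, 2 lower and 10 not passing, 7 and 2 when adjusted over the list alone, with a median of 0.74 that was -0.83 under core scaling. The regulator Cfh rose by 2.24 ± 0.38, the receptor gene C3ar1 by 1.58 ± 0.35 (-0.011 under core scaling) and properdin, Cfp, fell by 1.85 on the log2 scale (SE 0.29), with an adjusted p of 2.2e-03 for the list and an adjusted p of 0.359 with an estimated correlation. Without 5XFAD CD11c+ replicate 1 or 2 there were 0 or 1 higher pro-inflammatory genes and 0 or 1 higher complement genes, and without OPN-KO.5XFAD CD11c+ replicate 1 or 2 there were 1 or 2 and 1 or 1. With core scaling none was higher in these 3 lists, and 17 pro-inflammatory, 15 anti-inflammatory (median -1.12) and 4 complement genes were lower. Lower anti-inflammatory genes numbered 2 without any 1 of these 4 libraries, and higher complement genes 6 or 7 without 5XFAD CD11c- replicate 1 or 2.

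Of 9 osteopontin receptor genes none was higher, 2 were lower and 7 did not pass, 3 higher and 2 lower when adjusted over the list alone. The lower genes were Cd44, at 34.1 ± 1.29 CPM against 133 ± 7.50 (log2 fold change -1.97 ± 0.29 SE), and Itga4 at -2.03 ± 0.39. The list had a median of 0.07 and a mean of -0.06 (adjusted p = 0.902, and adjusted p = 0.952 with an estimated correlation). Monocyte markers took 0.0363% of counts in the knockout against 0.197% in 5XFAD, and dendritic cell markers 0.0179% against 0.0821%. B cell markers took 0.0738% against 0.0658%. Which cells carried the fall of Cd44 and Itga4 was not tested. Of 28 integrin and matrix adhesion genes 4 were higher, 5 lower and 19 not passing, 7 and 6 when adjusted over the list alone, with the fibronectin gene Fn1 at -1.87 ± 0.37 and the protease gene Adam10 at 1.61 ± 0.32 (adjusted p = 0.247, and adjusted p = 0.820 with an estimated correlation). Of 24 immediate-early and dissociation genes 4 were higher and 20 not passing, 8 higher when adjusted over the list alone, with Rgs1 at 1.68 ± 0.32, Atf3 at 1.60 ± 0.36 and a list median of 0.79 that was -0.80 under core scaling (adjusted p = 1.1e-05, and adjusted p = 0.359 with an estimated correlation). Of 17 unfolded protein genes 2 were higher, 8 when adjusted over the list alone, with the chaperone gene Pdia4 at 1.72 ± 0.36 and a median of 0.88 that was -0.72 under core scaling (adjusted p = 5.6e-05, and adjusted p = 0.359 with an estimated correlation). Lower osteopontin receptor genes numbered 1 without 5XFAD CD11c+ replicate 1, and 1 or 0 without OPN-KO.5XFAD CD11c+ replicate 1 or 2. Lower adhesion genes numbered 0 or 3 without 5XFAD CD11c+ replicate 1 or 2 and 1 or 0 without OPN-KO.5XFAD CD11c+ replicate 1 or 2. Without any 1 of these 4 libraries at most 1 immediate-early gene and no unfolded protein gene was higher, and without either 5XFAD CD11c- library 10 of each were. With core scaling none was higher in these 4 lists, and 5 osteopontin receptor (median -1.51), 17 adhesion (median -1.32), 11 immediate-early and 6 unfolded protein genes were lower.

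Of 13 lymphoid and T cell cross-talk ligands 2 were higher and 1 lower, 5 and 1 when adjusted over the list alone, with the checkpoint gene Lag3 at 1.63 ± 0.32 and the chemokine gene Ccl5 at -1.73 ± 0.40. That list had a median of 0.64, or -0.95 under core scaling (adjusted p = 2.7e-03, and adjusted p = 0.241 with an estimated correlation). In glycolysis 1 of 17 genes was higher and 1 lower, the same when adjusted over the list alone, Pfkp at -1.69 ± 0.30 being the lower (adjusted p = 0.872, and adjusted p = 0.952 with an estimated correlation). Of 26 cell cycle genes 1 was lower, Mki67 at -1.61 ± 0.35, and 6 when adjusted over the list alone (adjusted p = 0.0828, and adjusted p = 0.386 with an estimated correlation). Of 31 oxidative phosphorylation genes edgeR called none over all genes or when adjusted over the list alone, with 1 lower at an unadjusted p under 0.05 and 1 lower by DESeq2 (adjusted p = 0.290, and adjusted p = 0.866 with an estimated correlation). Without any 1 of the 4 CD11c+ libraries no cross-talk or glycolysis gene was higher and no cell cycle gene lower. Without either 5XFAD CD11c- library there were 5, 2 and 7. With core scaling none was higher in these 4 lists, and 5 cross-talk, 15 glycolysis (median -1.82), 26 cell cycle (median -2.23) and 31 oxidative phosphorylation genes (median -1.93) were lower.

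Among markers of other cell types every call but that of Cd79b was of a lower level in the knockout libraries. Of 12 astrocyte markers 11 were lower, also 11 when adjusted over the list alone, with Slc1a2 at -5.20 ± 0.47 and Aldoc at -4.85 ± 0.43 (adjusted p = 1.7e-24, and adjusted p = 0.209 with an estimated correlation). Of 12 monocyte markers 10 were lower, 11 when adjusted over the list alone, with S100a6 at -2.86 ± 0.37 and Ccr2 at -2.50 ± 0.31 (adjusted p = 2.1e-18, and adjusted p = 0.194 with an estimated correlation). Of 12 neutrophil markers 10 were lower, 11 lower and 1 higher when adjusted over the list alone, with Camp at -3.42 ± 0.40 and Cxcr2 at -3.17 ± 0.32 (adjusted p = 1.8e-17, and adjusted p = 0.194 with an estimated correlation). Of 12 dendritic cell markers 4 were lower, 5 when adjusted over the list alone, with Klrd1 at -2.49 ± 0.35 and Flt3 at -2.13 ± 0.40 (adjusted p = 2.1e-05, and adjusted p = 0.194 with an estimated correlation). Astrocyte, monocyte and neutrophil markers that were lower numbered 8, 5 and 6 without 5XFAD CD11c+ replicate 1, 6, 4 and 5 without OPN-KO.5XFAD CD11c+ replicate 1, and 5, 7 and 7 without OPN-KO.5XFAD CD11c+ replicate 2. Of 15 T and NK cell markers 4 were lower, 8 when adjusted over the list alone, with Nkg7 at -3.30 ± 0.48 (adjusted p = 2.4e-05, and adjusted p = 0.316 with an estimated correlation). Lower dendritic cell markers numbered 1 without 5XFAD CD11c+ replicate 1 or either OPN-KO.5XFAD CD11c+ library and 7 without 5XFAD CD11c- replicate 2. Lower T and NK cell markers numbered 1 without OPN-KO.5XFAD CD11c+ replicate 1 and 8 without either 5XFAD CD11c- library.

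Neuron markers had 3 of 12 lower, 8 when adjusted over the list alone, with Snap25 at -4.64 ± 0.52 (adjusted p = 3.9e-07, and adjusted p = 0.359 with an estimated correlation). Oligodendrocyte lineage markers had 6 of 11 lower, also 6 when adjusted over the list alone, with Mbp at -3.94 ± 0.64 (adjusted p = 7.6e-04, and adjusted p = 0.316 with an estimated correlation). The median of that list was -2.91, and -2.90 with Pdgfra, which had no count in the knockout libraries, at its bound. Endothelial and mural markers had 1 of 11 lower, 3 when adjusted over the list alone (adjusted p = 0.0330, and adjusted p = 0.316 with an estimated correlation). Border macrophage markers had 1 of 11 lower, also 1 when adjusted over the list alone, Clec10a at -1.58 ± 0.29, with a median of 0.16, or -1.44 under core scaling (adjusted p = 0.902, and adjusted p = 0.952 with an estimated correlation). B cell markers had 1 of 7 higher, Cd79b at 1.37 ± 0.35 (-0.23 under core scaling), also 1 when adjusted over the list alone (adjusted p = 0.0444, and adjusted p = 0.423 with an estimated correlation). Lower neuron markers numbered 5 without 5XFAD CD11c+ replicate 2 and 8 without either 5XFAD CD11c- library. Oligodendrocyte lineage markers had 1 lower without 5XFAD CD11c+ replicate 1 or either OPN-KO.5XFAD CD11c+ library. Endothelial and mural markers had 0 lower without either OPN-KO.5XFAD CD11c+ library and 3 without either 5XFAD CD11c- library. Clec10a no longer passed without 5XFAD CD11c+ replicate 1 or either OPN-KO.5XFAD CD11c+ library, and Cd79b without any 1 of the 4 CD11c+ libraries, while 2 B cell markers were lower with core scaling and 2 or 3 higher without 5XFAD CD11c- replicate 1 or 2.

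In the remaining 3 lists edgeR called no gene over all genes or when adjusted over the list alone. Erythroid markers had 2 of 6 higher at an unadjusted p under 0.05 and none by DESeq2 (median -0.01, mean 0.58, adjusted p = 0.417, and adjusted p = 0.801 with an estimated correlation). Ependymal and choroid plexus markers had none of 6 at an unadjusted p under 0.05 or by DESeq2 (adjusted p = 0.143, and adjusted p = 0.602 with an estimated correlation). Sex-linked genes had none of 5 at an unadjusted p under 0.05 or by DESeq2 (adjusted p = 0.393, and adjusted p = 0.707 with an estimated correlation). Without 5XFAD CD11c- replicate 1 or 2 there were 1 or 2 higher ependymal and choroid plexus markers and 1 higher erythroid marker. With core scaling 4 erythroid (median -1.57), 1 ependymal and choroid plexus (median -0.63) and 3 sex-linked genes (median -1.25) were lower.

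**Figure D4:**
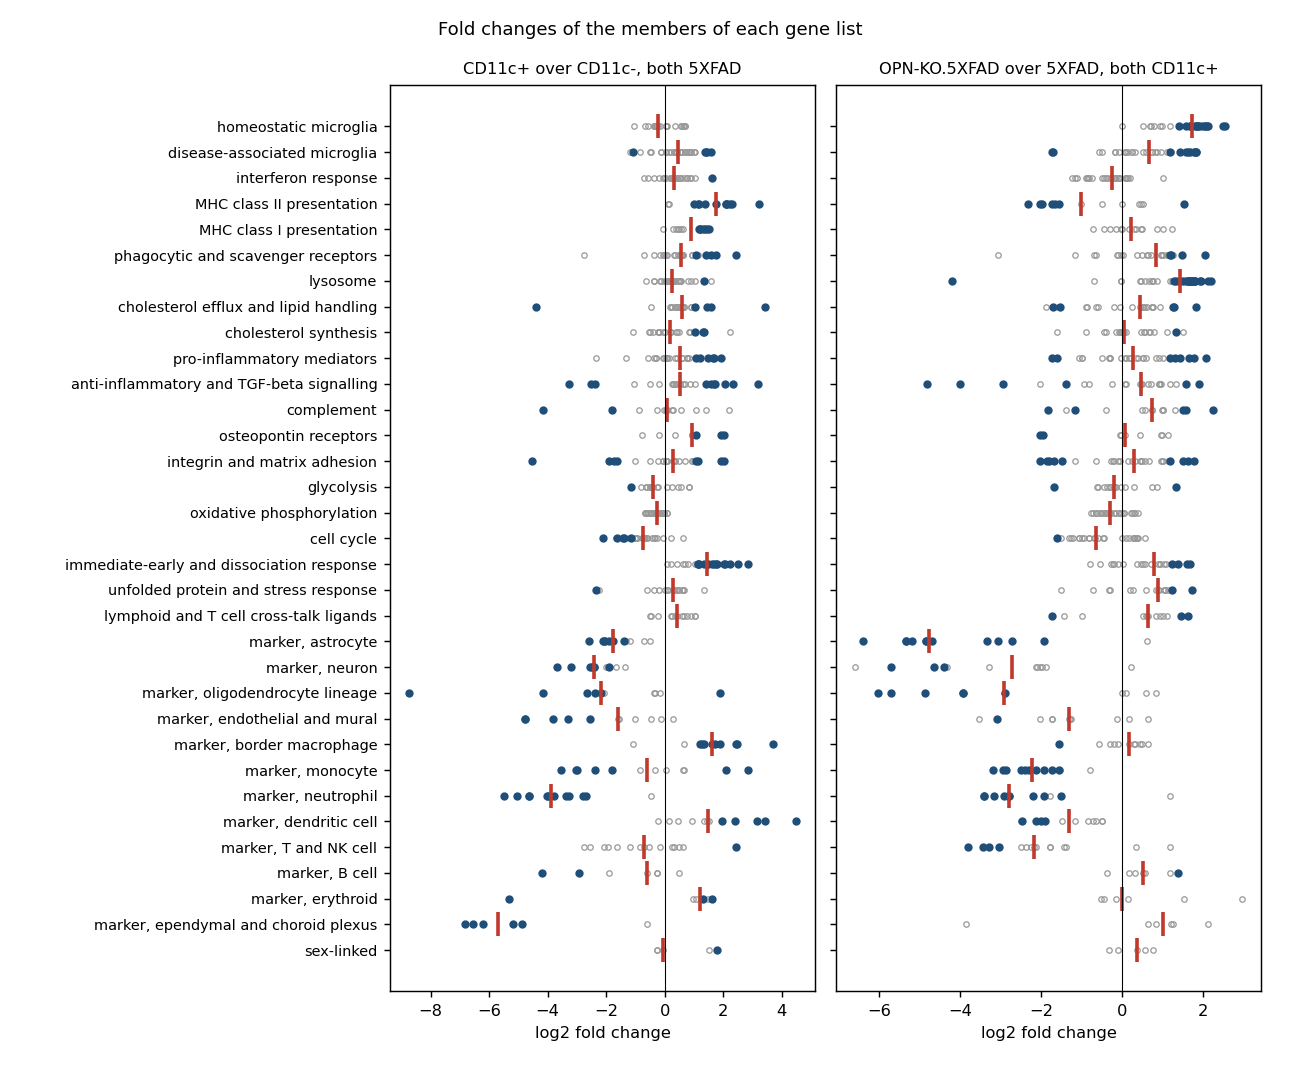
Log2 fold change of every tested member of the 33 lists in both comparisons. Filled points passed at an adjusted p under 0.05, open points did not, and the red bar is the list median. Neutrophil markers have a median of -3.88 between the fractions and -2.80 between the genotypes, and homeostatic genes -0.24 and 1.73 (0.13 between the genotypes under core scaling).

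Over all genes, 509 were higher and 882 lower in OPN-KO.5XFAD CD11c+, and 18506 did not pass. By the list tests 10 lists were higher and 9 lower, and none of the 19 calls held with an estimated correlation, a test that again rests on 3 residual degrees of freedom. The share of calls that were higher was 36.6%, and 0.198% with core scaling, where 22 genes were higher and 11064 lower, and the median log2 fold change of all genes was -0.14, against -0.27 with upper-quartile scaling and -1.73 with core scaling. Without 5XFAD CD11c+ replicate 1 or 2 there were 13 or 72 higher and 221 or 538 lower genes, and without OPN-KO.5XFAD CD11c+ replicate 1 or 2 there were 66 or 61 higher and 170 or 173 lower. Without 5XFAD CD11c- replicate 1 or 2 there were 1458 or 1492 higher and 1771 or 1776 lower, and a fit of only the 4 libraries compared gave 1356 and 1851.

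Of the genes within 10 Mb of Spp1, 13 of 215 passed (6.05%), against 1377 of 19681 elsewhere (7.0%). The odds ratio was 0.855 with a 95% confidence interval from 0.447 to 1.5 (two-sided Fisher's exact test, p = 0.687). That test counts calls of any size. Galnt9 at -8.19 ± 0.88 and Gm42602 at -4.26 ± 0.81 (log2, SE), chosen after their values were seen, lie within this window. Of the 33 genes that differed over 16-fold between genotypes and not between fractions, only these lie there. By the same exact test the odds ratio was 2.56 without OPN-KO.5XFAD CD11c+ replicate 1 (p = 0.0350) and 2.54 without replicate 2 (p = 0.0363).

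The log2 fold changes of both comparisons had a Pearson correlation of 0.268 across the 19897 genes, which are not independent replicates. Its sign turned with DESeq2 (-0.0225), with no filter (-0.0784) and without 5XFAD CD11c+ replicate 2 (-0.0874). Because the 5XFAD CD11c+ libraries enter both with opposite sign, simulations without any effect gave -0.452 on average, from -0.475 to -0.430. The genes lower in CD11c+ than in CD11c- and lower in the knockout numbered 333. Those higher in CD11c+ and lower in the knockout numbered 85, those lower in CD11c+ and higher in the knockout 23, and those higher in both 17. The libraries in common by themselves raise the number that move in opposite directions, so no overlap by chance is given for these counts, which were not recomputed under the alternatives. Among the 333 were neutrophil and astrocyte markers, and among the 85 were Ciita, Cd74 and Cd209a.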

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

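The alternatives without mitochondrial genes and with core scaling were chosen after the results were seen, and the others before the data were examined. With RLE scaling each count of called genes and lists, Spp1, Itgax, the correlation and the Spp1 neighbourhood kept their direction and side of the threshold or moved by less than 1.5 times. Of 129 named genes, 7 changed direction, all under core scaling between the genotypes. Such a change follows from the construction of that scaling for a gene with a small rise, since it took the median of all genes from -0.14 to -1.73. These were Cadm1 (-0.022), Mertk (-0.088), Gba (-0.094), Ccl4 (-0.18), C3ar1 (-0.011), Msmo1 (-0.26) and Cd79b (-0.23). Under core scaling 22 further named genes no longer passed, 5 between the fractions and 17 between the genotypes. Leaving out a single CD11c+ library lost more, with 20 and 42 lost without 5XFAD CD11c+ replicate 1, 28 and 26 without replicate 2, 5 and 32 without OPN-KO.5XFAD CD11c+ replicate 1, and 4 and 33 without replicate 2. Spp1 passed in the comparison of genotypes under every alternative, and when single libraries were left out it lay from -9.05 to -8.79, with adjusted p-values from 8.1e-09 to 1.1e-03 that do not follow that order. Itgax passed between the fractions, and when single libraries were left out it lay from 1.80 to 3.69, with adjusted p-values from 9.1e-05 to 0.0404.

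Between the fractions, where 931 genes were higher and 2309 lower, there were 599 higher with upper-quartile scaling, 1766 with no filter, 441 with the stricter filter and 332 with core scaling. The stricter filter gave 794 lower genes, of fewer tested. Between the genotypes, where 509 were higher and 882 lower, DESeq2 gave 908 higher, the fit of only 4 libraries 1356 higher and 1851 lower, no filter 1349 lower, and core scaling 22 higher and 11064 lower. Core scaling also gave 3 lists higher and 14 lower between the genotypes, in place of 10 and 9. Coded 1 for higher and -1 for lower, the list direction went from 1 to -1 there for pro-inflammatory mediators, for integrin and matrix adhesion, and for border macrophage markers. The counts of genes between the genotypes under core scaling follow from its shift of all genes. A list test sets members against other genes, so such a shift need not change its result. The cause of the list changes was not tested. Under core scaling the medians were -1.35 for pro-inflammatory mediators, -1.32 for integrin and matrix adhesion and -1.44 for border macrophage markers. Each lay above the median of all genes, -1.73. The stricter filter tests fewer genes, and the cause of the other changes was not tested.

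The correlation of both comparisons, 0.268, was -0.0225 with DESeq2 and -0.0784 with no filter, each over 38099 genes, 0.208 with only 4 libraries per fit, 0.258 without mitochondrial genes and 0.164 with core scaling. The odds ratio near Spp1 was 0.742 with core scaling (Fisher's exact test, p = 0.0322). As an added check for pairing, the replicate numbers are shared by all 3 groups, and the differences between replicates correlated at 0.183, 0.090 and 0.095 across pairs of groups. With the replicate block there were 1457 higher genes between the fractions, and 962 higher and 1362 lower between the genotypes.

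Without either 5XFAD CD11c- library, the pair with the lowest correlation between replicates, more genes were called between the genotypes than in the main fit. Fewer libraries thus did not always mean fewer calls. Leaving out a library leaves a group of 1, which is assumed to vary like the others. It lowers the residual degrees of freedom and changes the pooled spread of both comparisons. Between the fractions this gave 102 (without 5XFAD CD11c+ replicate 1) to 2281 (without 5XFAD CD11c- replicate 1) higher genes, 250 (without 5XFAD CD11c+ replicate 2) to 3203 (without 5XFAD CD11c- replicate 1) lower genes, 13 to 18 lists higher and 5 to 8 lower. Between the genotypes it gave 13 (without 5XFAD CD11c+ replicate 1) to 1492 (without 5XFAD CD11c- replicate 2) higher genes, 170 (without OPN-KO.5XFAD CD11c+ replicate 1) to 1776 (without 5XFAD CD11c- replicate 2) lower genes, 10 to 12 lists higher and 8 to 11 lower. The correlation ran from -0.0874 (without 5XFAD CD11c+ replicate 2) to 0.284 (without OPN-KO.5XFAD CD11c+ replicate 2), and the odds ratio near Spp1 from 0.783 to 2.56 and 2.54 (without OPN-KO.5XFAD CD11c+ replicate 1 and 2). With 2 libraries a group, a 2-fold change was called for 1 and 3 of 67 simulated genes. Fewer genes were called in the simulation than in the real libraries, which makes its threshold stricter, so these shares can be too low. A gene that did not pass can still differ by 2-fold.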

Other observations

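All tests of explanations given here were chosen only after the results were seen, and the gene families were picked from the table of genes. Immunoglobulin genes, the products of B cells and plasma cells, were higher in the OPN-KO.5XFAD CD11c+ libraries for 11 of 44 tested and lower for none (median 0.91), and 17 of them were lower in 5XFAD CD11c+ than in 5XFAD CD11c- while none was higher. Their summed share of counts was 0.0639% and 0.0650% in the 5XFAD CD11c+ libraries, 0.0744% and 0.0862% in OPN-KO.5XFAD CD11c+, and 0.0652% and 0.0854% in 5XFAD CD11c-. With core scaling 13 were higher and 10 lower in the knockout libraries and the median was -0.73. The 11 became 4 or 5 without 5XFAD CD11c+ replicate 1 or 2 and 6 or 4 without OPN-KO.5XFAD CD11c+ replicate 1 or 2, and the 17 became 3 or 5 and 9 or 8. Klra genes, receptors of natural killer cells, were lower in the knockout libraries for 6 of 12 tested and higher for none, but for 1 without either 5XFAD CD11c+ library and for none without either OPN-KO.5XFAD CD11c+ library. Prl, the pituitary hormone prolactin, had 170 and 97 counts in 5XFAD CD11c+, 125 and 42 in 5XFAD CD11c- and none in OPN-KO.5XFAD CD11c+.

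All 13 protein-coding genes of the mitochondrial genome were lower in 5XFAD CD11c+ than in 5XFAD CD11c-, with a median of -5.05, and none passed between the genotypes with edgeR or DESeq2, though 11 were lower there with core scaling. Of 215 olfactory receptor genes tested, 111 were lower in CD11c+ than in CD11c- and none was higher (median -4.48). Their share of counts was 0.0408% in 5XFAD CD11c- replicate 1 and 0.202% in replicate 2, the library with the fewest counts. Without replicate 2 there were 27 lower and 2 higher of 191, and without replicate 1 there were 212 lower of 357. Leaving out 5XFAD CD11c+ replicate 1 or 2 gave 1 or 5 lower, and leaving out OPN-KO.5XFAD CD11c+ replicate 1 or 2 gave 33 or 38. The nuclear long noncoding RNA Malat1 was at 6279 ± 924 CPM (SD, n = 2) in 5XFAD CD11c+, 1682 ± 101 in OPN-KO.5XFAD CD11c+ and 1675 ± 643 in 5XFAD CD11c-.

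In the OPN-KO.5XFAD CD11c+ libraries 16 of 24 homeostatic and 20 of 37 lysosomal genes were higher and 1 lysosomal gene was lower, while 11 of 12 astrocyte, 10 of 12 monocyte and 10 of 12 neutrophil markers were lower, and none of these list tests held with an estimated correlation. A lower share of microglia against all other cells alike in 5XFAD CD11c+ would move other markers together, but 6 marker medians spanned 5.29 log2 units, against a mean SD of list members of 0.980, from -4.77 for astrocytes to 0.52 for B cells. RNA of some other cell types diluting microglial RNA there is a candidate explanation. With 5 core microglial genes set equal the median of the other homeostatic genes was 0.067 (SD 0.67, 22 genes) and that of lysosomal genes -0.22 (SD 1.11, 36 genes), but 3 of the 5 core genes were themselves higher in the knockout, so dilution cannot be told apart from a rise of all these genes with the loss of osteopontin. Under that scaling disease-associated genes had a median of -0.91, complement genes -0.83 and phagocytic receptors -0.75, while P2ry12 was still 0.94 above 5XFAD and P2ry13 0.90.

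Of 12 neutrophil markers 11 were higher in 5XFAD CD11c-, where S100a8, S100a9 and Ngp reached 20039, 18732 and 13350 CPM. Neutrophil RNA in these libraries is a candidate explanation, although a gate for microglia is meant to leave out neutrophils and whether this one did is not known. All 13 genes of a second set of neutrophil genes, from granule proteins to receptors and in none of the 33 lists, were higher there too (median of CD11c+ over CD11c- -2.72, SD 0.76). Of these Lcn2 was at 3174 CPM against 189 in 5XFAD CD11c+. The 13 became 8 or 7 without 5XFAD CD11c+ replicate 1 or 2. A shift of the scaling by the mitochondrial reads of these libraries does not account for the pattern, since such a shift moves every gene alike and the median of the 12 markers listed beforehand less that of all genes was -3.73 (SD 1.33). Whether CD11c- microglia of these brains transcribe such genes was not tested, since the counts come from bulk libraries.

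Trim5, Trim12a, Trim30d and Gm1966, all within 5 Mb on chromosome 7, were near absent in OPN-KO.5XFAD CD11c+ and present in both 5XFAD groups. A lower interferon response does not account for all of it, since the median of that list was -0.25 (SD 0.51, 26 genes). Under core scaling that median was -1.85, where all genes had a median of -1.73 and these 4 genes lay from -9.78 to -6.54. Reads moving between near-identical Trim copies do not account for all of the fall in the Trim genes. The sum of 9 Trim genes there still fell by 1.07 on the log2 scale, against a largest SD between replicates of a group of 0.288. That sum leaves out Gm1966 and cannot show reads that were not counted at all. A segment of another strain, which changes sequence or copy number, may be carried by the knockout mice. Among 33 genes that differed over 16-fold between genotypes and not between fractions, no window of 5 Mb held more than these 4 (permutation p = 0.0059), but among all 87 genes that differed as much, fractions set aside, the p was 0.209. The first set was picked after the second had been seen, genes that share sequence are not independent, and genotype is confounded with any such segment, so it cannot be told apart from an effect of osteopontin.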
